A study of Mus musculus with 4 samples.

How the data were processed

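Gene expression was measured in 4 samples of mouse embryo tissue at embryonic day 8.5, per the labels. ARC/s embryos with 4 to 5 somites were dissected, and 15 to 20 pieces of the same tissue were pooled for each sample, per the labels' protocols. A source label gives a slightly wider somite range than the other labels. The samples were labelled as 2 of foregut endoderm, taken from the anterior intestinal portal per the series' design text, and 2 of heart mesoderm combined with head mesoderm and ectoderm. The work was done in 2 experiments, each with 1 sample of either tissue. Tissues numbered 1 were separated by hand and tissues numbered 2 were treated with trypsin and pancreatin first, per the labels' protocols, whereas the series' design text describes enzyme treatment without naming an experiment. In these samples the experiment and the way of dissection cannot be told apart. In 1 description field, foregut endoderm 2 is called ectoderm, while its title, source and tissue labels name foregut endoderm, which was used here.

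RNA was purified on columns, amplified linearly in 2 rounds, labelled with biotin and hybridized to Affymetrix mouse MOE430 arrays, per the labels' protocols and the series' design text. The deposited values are intensity values per probe set, made by the authors with GC-RMA in GenePattern, per the series' design text, and RMA is the tool named per the submitters' processing notes. Versions, parameters and the annotation used by the authors are not given in the sources used here. The scale is not named either and was read from the values, which ran from 4.75 to 75550 with a median near 6 on each array, as linear intensities do. Between 41.3% and 44.7% of the probe sets of an array lay within 0.1 log2 units of that array's lowest value, called the floor here. A fold against a group whose arrays were all at that floor is given as a lower bound ("at least"). A difference with 1 array of a group at the floor is called a bound in size. Other dim probe sets lay at levels of their own that moved between arrays only as the lowest values did. Wnt6, for example, was at 3.087 and 3.104 in foregut endoderm 1 and 2 and at 3.118 and 3.122 in mesoderm and ectoderm 1 and 2. Differences against such a level are bounds too, and the rule does not mark all of them.

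The table held 45101 probe sets, of which 64 were Affymetrix controls and were left out of tests. GEO's platform annotation gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211, and probe sets with several were not named. Of those with 1 symbol, 34754 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed by the match. That table served for names and gene lengths only. Values were set to at least 1, which altered none, and log2 was taken here. Probe sets with a log2 value above 5 on at least 2 of the 4 arrays were kept, which left 13288, of which 11899 had 1 symbol. For work on genes the probe set with the highest mean was taken, which gave 7802 genes. Between 12470 and 13033 probe sets of an array lay above the filter, and no pair of arrays held identical values. Only 2 arrays per tissue limit the precision of every value.

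Tissues were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), as foregut endoderm minus mesoderm and ectoderm, without a term for the experiment. Standard errors (SE) of tissue differences are from this fit unless said otherwise. They therefore include any shift that both tissues shared between the experiments. Experiments were compared as second minus first with tissue as a term. As each experiment holds a comparison of its own, probe sets at least 2-fold apart in the same direction in both experiments were also counted, with no test. The 20 gene lists, with 355 entries in all, were tested with limma's camera (preset correlation 0.01), with camera with an estimated correlation and with fry, adjusted over the lists. Some genes stand in several lists, such as Foxa2 and Shh in the endoderm and the notochord lists. The lists, the tests, the alternative settings and the rule for named genes were fixed before the data were examined. The rule took, in each direction, 12 genes past the test with the same sign in both experiments and, where too few passed, the next by moderated t; up to 4 members with the smallest p from each list; and, between experiments, the 5 genes with the smallest p in each direction. This gave 88 genes for the tissues, of which 34 had more than 1 kept probe set. In 1 of them, Egfl7, the mean tissue differences of those probe sets differed in sign. That check covered the sign only, and probe sets of the same gene could differ widely in size. Genes named outside the rule are said to have been chosen after their values were seen.

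The sample numbers pair the samples, because the labels' protocols say that tissues of the same number were dissected in the same way, as 1 of the 2 experiments. The deviations of same-numbered arrays from their tissue means had a correlation of 0.56 across probe sets. A fit with the replicate number as a block was therefore run as an alternative and is given where it changed a call or moved a count of calls by over 1.5 times. It left 1 residual degree of freedom, against 2 without the block. Labels speak of pooled tissue from 2 experiments and do not name separate litters, so p-values measure only the spread between these samples.

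The limma step was tested on simulated data for the tissue comparison with 13288 probe sets, of which 50 at each fold were changed. With an experiment effect of the size seen in the real arrays, the fit without the block recovered 0% of the 16-fold changes. The fit with the block recovered 56% of the 4-fold, 90% of the 8-fold and 100% of the 16-fold changes. It also called 20 unchanged probe sets. Noise was drawn from a normal distribution, and the experiment effect was equal in both tissues. Genes with opposite tissue differences in the 2 experiments were thus not simulated, and these shares may not hold for the real arrays. With no experiment effect, the fit without the block recovered 74% of the 4-fold and 98% of the 16-fold changes, with 13 unchanged probe sets called. Alternatives were quantile normalization, median centring, no filter, a stricter filter (log2 above 7), a mean-variance trend with robust eBayes, the mean of all probe sets of a gene, the block, a pseudocount of 16, other thresholds and leaving out each array in turn. Another background correction could not be tried on summarized values. Lists of cardiac transcription regulators, sarcomere proteins, pharyngeal endoderm genes and proteases with their inhibitors were written after the values were seen, and only the first 2 are described, among the additional observations. Figures were drawn with matplotlib 3.10.9.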

Results

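The data were 4 microarray profiles of mouse embryos at embryonic day 8.5, when the gut tube begins to fold in at its front end. They comprised 2 samples labelled as foregut endoderm and 2 labelled as heart mesoderm pooled with head mesoderm and ectoderm, with 1 sample of each tissue in either experiment. Across the 13288 kept probe sets, arrays resembled each other more by experiment than by tissue. Pearson's r across probe sets was 0.93 between the tissues of the first experiment and 0.91 between those of the second, against 0.87 between the foregut endoderm arrays and 0.81 between the mesoderm and ectoderm arrays. Median intensity lay between 5.72 and 6.15 on the 4 arrays.

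The first question was which genes mark foregut endoderm against its neighbouring tissues. Among the 12 genes ranked first by moderated t on the higher side were transcription factors of the gut and its pharyngeal part. Foxa1, a forkhead factor of gut endoderm (probe set 1418496_at), had a log2 intensity of 10.87 ± 0.07 in foregut endoderm and 4.51 ± 0.54 in mesoderm and ectoderm (mean ± SD, n = 2), a difference of 6.36 ± 0.40 (SE), or 82.1-fold. Pax9, a paired-box factor of the pharyngeal pouches (probe set 1442229_at), was at 9.65 ± 1.19 in endoderm and at the array floor in both other samples. This probe set was thus at least 162-fold higher in endoderm. Its log2 difference of 7.34 ran from 6.50 to 8.18 with each array left out in turn. The other kept probe set of Pax9 differed by only 3.08 log2 units (2.81 in the first experiment and 3.36 in the second). The 162-fold bound therefore holds for the brighter probe set alone. Prdm1, a transcriptional repressor of early endoderm and germ cells, lay 3.46 ± 0.36 log2 units higher in endoderm.

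Apart from the noncoding Airn, the other leading genes encoded secreted, surface and metabolic proteins. Afp, the alpha-fetoprotein of yolk sac and fetal liver, was 40.6-fold higher in foregut endoderm (log2 difference 5.34 ± 0.56, SE). Masp1, a serine protease of the lectin complement pathway, differed by 4.59 ± 0.38. That is a lower bound, as Masp1 outside the endoderm (2.711 and 2.716) moved only as the arrays' lowest values did. Arg1, the arginase of the urea cycle, was at least 24.8-fold higher, because it sat at the floor outside the endoderm. Differences were 3.32 ± 0.30 for Frem1, an extracellular matrix protein, and 3.77 ± 0.31 for Airn, the noncoding antisense transcript of the imprinted Igf2r locus. Those of Moxd1, Scara3 and the tight junction gene Cldn4 lay at 2.99, 2.73 and 2.85. The value of Scara3 is a lower bound too, as this gene outside the endoderm (4.329 and 4.333) moved only as the arrays' lowest values did. Slco4c1, an organic anion transporter, was at least 6.49-fold higher but reached a log2 intensity of only 5.03 in endoderm, just above the filter.

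On the other side, genes lower in foregut endoderm were led by patterning factors of the anterior neural plate. Emx2, a homeobox factor of the forebrain (probe set 1456258_at), was at the floor on both endoderm arrays and at 6.97 ± 0.14 (SD, n = 2) in mesoderm and ectoderm, hence at least 26.3-fold lower in endoderm. Fezf1, a zinc finger factor of the forebrain, and Zic1 were each at the floor on 1 of the endoderm arrays, so their log2 differences of -5.12 and -4.90 are lower bounds in size. The differences were -2.92 ± 0.29 (SE) for Otx1 and -2.75 ± 0.36 for Six3, which both act in forebrain development. That of Otx1 is a bound in size, as its endoderm values (3.515 and 3.532) moved only as the arrays' lowest values did. They were -5.39 ± 0.72 for Sp8, a zinc finger factor of the anterior neural ridge, and -4.81 ± 0.57 for Pax3, a factor of the dorsal neural tube and neural crest. The other genes among these 12 were the synaptotagmin gene Syt11 at -4.24, the kinase gene Pak3 at -4.16, the tachykinin precursor Tac1 at -3.28, the DM-domain transcription factor gene Dmrta1 at -3.25 and the sialyltransferase St8sia3 at -3.08.

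None of these genes passed the test. With limma, 0 of 13288 probe sets had an adjusted p under 0.05 in either direction, and the lowest was 0.724; at an unadjusted p under 0.05, 395 were higher and 105 lower in endoderm, against 664 in all given by chance. At the level of 7802 genes limma called 0 as well, with 353 at an unadjusted p under 0.05 against 390 by chance, and the lowest adjusted p was 0.475, shared by Foxa1, Pax9, Afp, Emx2, Fezf1 and all others named so far except Pak3 (0.509). With the replicate number as a block, limma called 0 probe sets too, while 968 were higher and 358 lower at an unadjusted p under 0.05 and the lowest adjusted p was 0.352, and of the genes it called 0, with 637 higher and 265 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.223. The spread between the experiments enters the error of the fit without the block. In the simulation with an experiment effect, that fit recovered 0% of the 16-fold changes. Its count of 0 therefore does not show that the tissues are alike. The count of 0 with the block does not show it either, since the recovery simulated for that fit may not hold for these arrays.

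The experiments can also be set side by side without a test. At least 2-fold differences in the same direction in both experiments were found for 607 probe sets, of which 474 were higher and 133 lower in endoderm, where independent lists would share 171 and 31. The split moved with the scaling, as quantile normalization gave 367 higher and 194 lower and median centring 347 higher and 211 lower. The median difference of all probe sets moved with it, from 0.10 as deposited to -0.02 and -0.08. Among genes, 276 were higher and 97 lower, and at 4-fold these counts were 81 and 39. The genes past 4-fold in both experiments included Foxa1 (6.79 and 5.93 log2 units), Pax9 (6.50 and 8.18), Afp (5.10 and 5.58), Emx2 (-4.82 and -4.61) and Fezf1 (-5.72 and -4.51), where the values of Pax9 and Emx2 and the first of Fezf1 are bounds in size, set by the floor. Opposite signs occurred too, as 213 probe sets were at least 2-fold higher in endoderm in the first experiment and at least 2-fold lower in the second, against 101 by independence, and 62 went the other way, against 52.4. Among genes these counts were 153 against 67.5 and 5 against 19.2. Across probe sets the differences of the 2 experiments had a Pearson's r of 0.14 and a Spearman's rho of 0.24, and probe sets are not independent replicates. With 1 array left out, 954 probe sets passed 2-fold without foregut endoderm 1, 820 without foregut endoderm 2, 1622 without mesoderm and ectoderm 1 and 1143 without mesoderm and ectoderm 2, where the lone array then served both comparisons.

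The fixed lists sort these genes by tissue of origin. Of the 20 genes fixed as foregut and definitive endoderm markers, 11 were measured, and 10 of them were higher in foregut endoderm in both experiments. Median log2 differences were 3.29 in the first experiment and 3.71 in the second. Beside Foxa1 and Prdm1, the transmembrane serine protease Tmprss2 differed by 6.14 ± 0.74 (SE), the membrane carboxypeptidase Cpm by 4.76 ± 0.59, Foxa2 by 3.57 ± 0.50 and the morphogen Shh by 3.43 ± 0.79. Adjusted over the list alone, 8 members passed limma's test, all higher, and with the replicate number as a block 9 did, Hhex (chosen after its values were seen) being added, against 0 over all genes either way. In limma's camera the list stood above other genes with an adjusted p of 1.6e-14, and the adjusted p was 0.342 with an estimated correlation. Without a filter its mean fell from 3.53 to 2.25, and limma's adjusted p was 4.6e-10. Foregut endoderm 2, called ectoderm in 1 of its labels, had Foxa1 at 10.82 and Foxa2 at 8.61, against 10.92 and 7.52 in foregut endoderm 1.

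Epithelial genes followed the same direction. All 18 measured genes of epithelial junctions and keratins were higher in endoderm in both experiments, with medians of 2.10 and 2.91. The adherens junction gene Cdh1 differed by 3.41 ± 0.60 (SE), the splicing regulator Esrp1 by 2.39 ± 0.51 and the transcription factor Grhl2 by 1.98 ± 0.49. Only Cldn4 passed when adjusted over the list alone, and 14 members did so with the replicate number as a block, with 0 over all genes either way. The list's adjusted p was 1.27e-11 in limma's camera and adjusted p = 0.342 with an estimated correlation, and its mean of 2.38 fell to 1.40 without foregut endoderm 2 (limma's adjusted p = 1.32e-05).

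Of the yolk sac visceral endoderm genes 6 of 20 were measured, and 5 of these were higher in foregut endoderm in both experiments. Ttr, the transthyretin carrier, differed by 5.90 ± 1.70 (SE), Rbp4, the plasma retinol carrier, by 2.39 ± 1.11 and Mttp, which loads lipid onto lipoproteins, by 1.43 ± 0.31. With the replicate number as a block, which left 1 residual degree of freedom, these SE were 0.51, 0.57 and 0.22. Ttr ran from 3.92 to 7.89 and Rbp4 from 1.00 to 3.79 with each array left out in turn. Another 11 members, among them the apolipoprotein gene Apob, were below the filter, and the highest endoderm value among those was 4.20. Adjusted over the list alone, Afp and Mttp passed, and with the block 4 were higher and 1 lower, against 0 over all genes. Limma's camera gave the list an adjusted p of 0.000699, and adjusted p = 0.342 with an estimated correlation, and without a filter its mean fell from 2.51 to 1.00 (limma's adjusted p = 0.000904). Among notochord and prechordal plate genes only Foxa2 and Shh were measured, both shared with the endoderm list, and both passed over the list alone, with 0 over all genes. That list had a camera adjusted p of 0.00031 in limma, and adjusted p = 0.342 with an estimated correlation. Its call was lost without a filter, where more of its members entered and the mean fell from 3.50 to 0.98 (limma's adjusted p = 0.172).

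Neural plate genes lay lower in foregut endoderm. Of 17 measured members, 12 were lower in both experiments and 2 were higher, with medians of -2.08 and -2.39. Fezf1, Otx1, Zic1 and Six3 were the members with the smallest p, and adjusted over the list alone 8 members were lower and 1 higher, and with the block 10 were lower, Hesx1 and Sox1 (chosen after their values were seen) being added, and 1 higher, against 0 over all genes either way. Limma's camera placed the list below other genes with an adjusted p of 9.47e-15, and adjusted p = 0.342 with an estimated correlation. Without a filter, where 24 members entered, limma's camera gave a weaker adjusted p of 1.6e-05. Of 9 neural crest genes, 7 were lower in both experiments, with medians of -0.41 and -3.51. Pax3 was the member that passed over the list alone, the SoxE factor Sox10 differed by -0.94 ± 0.32 (SE) and the AP-2 factor Tfap2a by -3.31 ± 1.37, whereas Erbb3, a neuregulin receptor, was at 1.08 ± 0.50. Leaving out each array in turn gave -5.07 to -1.55 for Tfap2a and 0.51 to 1.64 for Erbb3. The crest list had a camera adjusted p of 1.6e-05 in limma, and adjusted p = 0.342 with an estimated correlation, and its mean of -1.63 shrank to -0.93 without foregut endoderm 2 (limma's adjusted p = 0.000476). Of surface ectoderm and placode genes only 3 were measured, and over the list alone Tfap2c (-3.29) and Dlx5 (-1.45) were lower and Eya1 (1.68) was higher, with 0 over all genes, and Dlx5 no longer passed with the block. As a list they did not pass camera (limma's adjusted p = 0.0807).

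**Figure D1:**
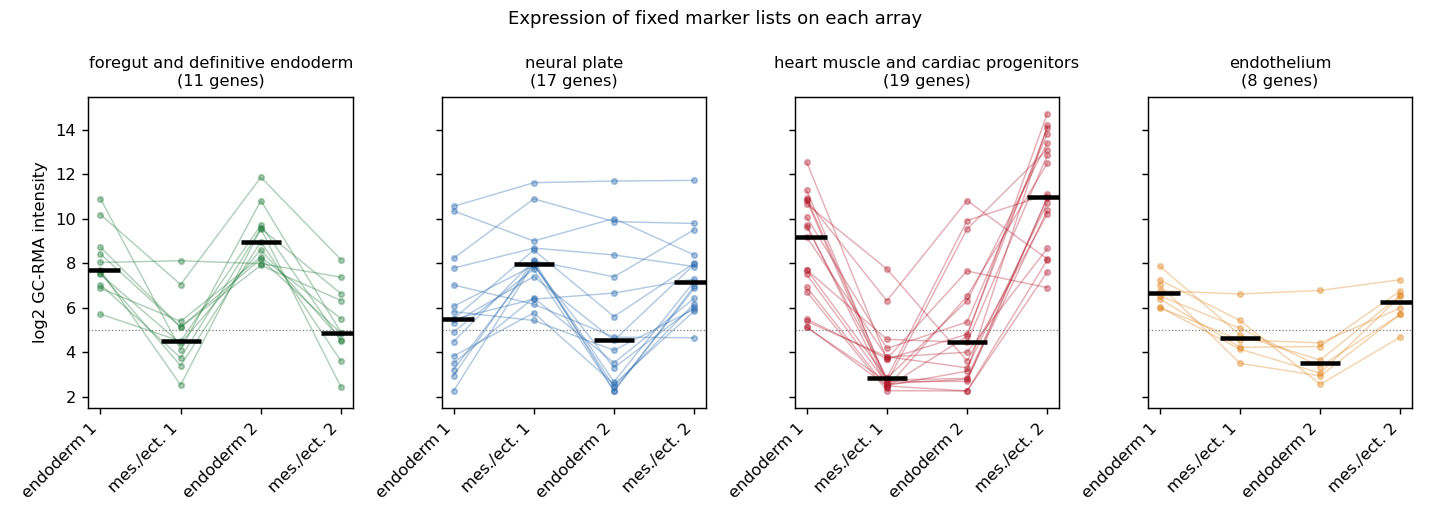
Log2 GC-RMA intensity (vertical axis) of the measured members of 4 fixed marker lists on each of the 4 arrays (horizontal axis). Thin lines join the arrays for each gene, thick bars are medians and the dotted line is the filter at 5; the endoderm medians exceed 7 on both endoderm arrays, while the heart median is 2.83 on mesoderm and ectoderm 1 and 10.98 on mesoderm and ectoderm 2.

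Heart and vessel genes and 2 embryonic globins went opposite ways in the experiments. The median log2 difference of the 19 measured heart muscle and cardiac progenitor genes was 4.89 in the first experiment, higher in endoderm, and -7.10 in the second, lower in endoderm, and 17 of the 19 switched sign in this way. Their median log2 intensity was 2.83 in the sample labelled mesoderm and ectoderm 1, against 10.98 in mesoderm and ectoderm 2. It was 9.19 in foregut endoderm 1 and 4.45 in foregut endoderm 2. The filter asked for a value above 5 on at least 2 arrays, so heart genes high in mesoderm and ectoderm 2 alone were left out. Nppa, Csrp3 and Actn2 were such genes, at 9.06, 9.01 and 8.03 there and 3.14, 4.06 and 3.12 in foregut endoderm 1. These medians therefore lean towards heart genes that were also high on another array. Myl2, a ventricular myosin light chain, was at 1.59 and -7.40, and Tnni1, the slow skeletal troponin I of the embryonic heart, at 2.43 and -8.28. In values chosen after they were seen, cardiac troponin T (Tnnt2) had log2 intensities of 10.84 in foregut endoderm 1, 2.51 in mesoderm and ectoderm 1, 3.16 in foregut endoderm 2 and 14.20 in mesoderm and ectoderm 2, and the atrial light chain Myl7 had 9.74, 2.44, 4.72 and 14.74. Isl1, a factor of the second heart field and of pharyngeal endoderm, was higher in endoderm in both experiments (4.53 and 2.63), and Tbx20 was at 9.65 and 9.93 on the endoderm arrays, 2.85 in mesoderm and ectoderm 1 and 11.10 in mesoderm and ectoderm 2.

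All 8 measured endothelial genes switched sign as well, with medians of 1.85 and -2.43, among them Erg (3.50 and -2.78), Esam (1.89 and -3.46), Flt4 (1.46 and -2.35) and Egfl7 (0.14 and -0.48). The embryonic globins Hbb-bh1 and Hbb-y were at 2.42 and 2.72 in the first experiment and at -3.93 and -3.44 in the second. They were the only measured members of the 13 genes in the red blood cell list. Of those below the filter, Alas2 and Hba-a1 were at the floor on all 4 arrays. Hba-x left it only in mesoderm and ectoderm 2 (4.73). Head and trunk mesenchyme was divided, with medians of 2.04 and -1.77 over 13 genes. Tbx1, active in pharyngeal endoderm and mesoderm, differed by 3.21 ± 0.43 (SE) and was the member that passed over the list alone, while Prrx1 was at 1.60 ± 0.43, Pdgfrb at 1.52 ± 0.85 and Zeb2 at -2.15 ± 1.35. Pdgfrb ran from 0.53 to 2.51 and Zeb2 from -3.89 to -0.42 with each array left out in turn.

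None of these lists passed limma's camera, at adjusted p = 0.322 for heart and for endothelium, 0.448 for red blood cells and 0.803 for mesenchyme, and 0 of their members passed over all genes. Single arrays decided the sign of the mean differences. The heart mean of -0.48 became -2.23 without foregut endoderm 1 (limma's camera adjusted p = 0.0356), 1.27 without foregut endoderm 2 (0.649), -4.33 without mesoderm and ectoderm 1 (3.19e-09) and 3.37 without mesoderm and ectoderm 2 (2.12e-06). Without foregut endoderm 1 the means were -1.59 for endothelium (limma's adjusted p = 9.56e-05) and -1.37 for mesenchyme (0.000324), and without foregut endoderm 2 they were 1.26 (0.0293) and 1.39 (2.31e-05). These calls were made at the preset correlation only. With an estimated correlation, in limma's camera, the adjusted p was 0.823 for heart without foregut endoderm 1, 0.738 without mesoderm and ectoderm 1 and 0.593 without mesoderm and ectoderm 2, 0.51 and 0.741 for endothelium and 0.51 and 0.619 for mesenchyme without the endoderm arrays in turn, and with all arrays it was 0.87 for heart, 0.812 for endothelium and 0.969 for mesenchyme.

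**Figure D2:**
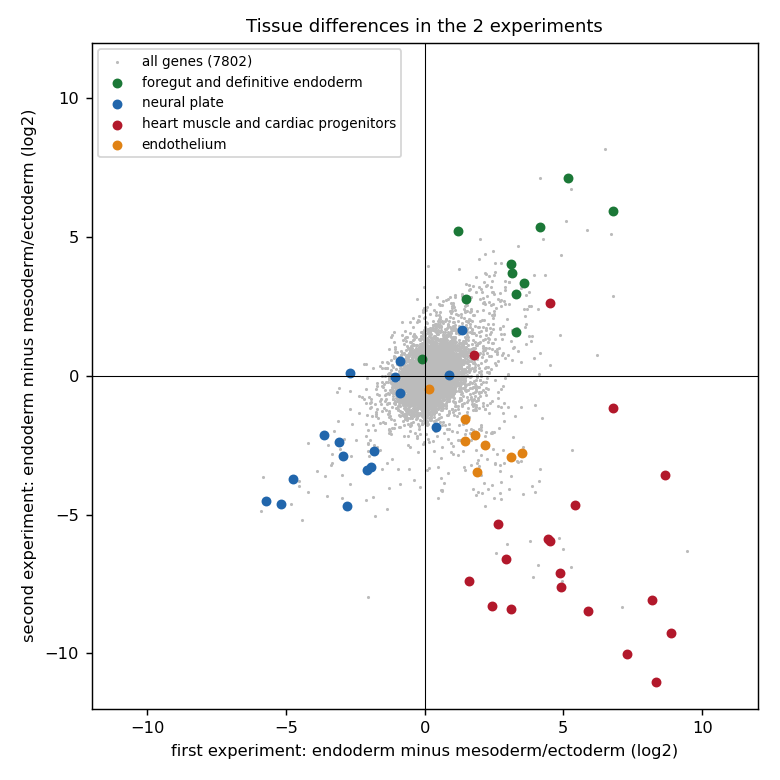
Log2 difference, foregut endoderm minus mesoderm and ectoderm, of each of 7802 genes in the first experiment (horizontal axis) and in the second (vertical axis), with members of 4 fixed lists in colour. Endoderm genes lie mostly at upper right (medians 3.29 and 3.71), neural plate genes mostly at lower left (-2.08 and -2.39), and 17 of 19 heart genes at lower right.

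In the FGF list, 6 of 7 measured genes were higher in endoderm in both experiments, led by the FGF target genes Etv5 (2.37 ± 0.33, SE) and Dusp6 (2.18 ± 0.33), which both passed over the list alone, with Spry1 at 1.36 ± 0.76 and Fgfr1 at 0.97 ± 0.98. Spry1 ran from 0.39 to 2.33 and Fgfr1 from -0.02 to 1.96 with each array left out in turn. Of 11 WNT pathway genes 7 were lower in both experiments, such as the WNT target Axin2 (-1.62 ± 0.41), the receptor Fzd5 (-2.37 ± 0.48) and the ligand Wnt5b (-1.52 ± 0.49), whereas the ligand Wnt5a was at 1.71 ± 0.36. Over the WNT list alone 0 passed in limma, with 1 higher and 3 lower at an unadjusted p under 0.05, and with the block 1 was higher and 3 lower. Over all genes 0 members of either list passed.

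Limma's camera gave FGF genes an adjusted p of 0.0122 and WNT genes 0.028, and adjusted p = 0.342 for both with an estimated correlation. The mean differences were 0.93 for FGF and -0.45 for WNT. The replicate block, which leaves the means as they are, ended both calls (limma's adjusted p = 0.0634 for FGF and 0.0766 for WNT). They were also lost without foregut endoderm 1 (means 0.81 and -0.50, limma's adjusted p = 0.0575 and 0.0578) and without a filter (means 0.56 and -0.13, limma's adjusted p = 0.0884 and 0.835). The FGF call was lost without mesoderm and ectoderm 2 (mean 0.61, limma's adjusted p = 0.221), and the WNT call without mesoderm and ectoderm 1 (mean -0.35, limma's adjusted p = 0.264), with median centring (mean -0.62, limma's adjusted p = 0.0905) and with the stricter filter (mean -0.18, limma's adjusted p = 0.529).

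Of 8 hedgehog pathway genes, Ptch1, the receptor and target gene of hedgehog, was 5.68-fold higher in endoderm (2.51 ± 0.32, SE) and passed over the list alone. Shh joined it with the block, both against 0 over all genes. Gas1, a hedgehog co-receptor, was at -1.09 ± 0.53 and Smo at 0.46 ± 0.30, and the list's median of -0.02 differed in sign from its mean of 0.53, which ran from 0.29 to 0.76 with each array left out in turn. Among 12 BMP and TGF-beta genes 0 passed over the list alone in limma and 1, Tgfb2, had an unadjusted p under 0.05. Tgfb2 was at 4.84 ± 1.51, Smad7 at 1.56 ± 0.89, Bmp5 at -1.26 ± 0.77 and Bmper at -1.22 ± 0.75. With each array left out in turn these ran from 2.79 to 6.88 for Tgfb2, from 0.49 to 2.63 for Smad7, from -2.22 to -0.30 for Bmp5 and from -2.13 to -0.30 for Bmper. The retinoic acid list had Aldh1a2, the enzyme that makes retinoic acid in the embryo, at -1.40 ± 0.50, its counterpart Cyp26a1, which degrades it, at 1.22 ± 0.57 and Crabp2 at -1.64 ± 1.32. With each array left out in turn these ran from -1.92 to -0.87, from 0.66 to 1.78 and from -2.92 to -0.36, and Gas1 from -1.61 to -0.57. Over that list alone limma called 0 of 6 members, with 0 at an unadjusted p under 0.05, and with the block 2 were higher and 2 lower. As lists these did not pass limma's camera, with adjusted p = 0.448 for hedgehog and for retinoic acid and 0.951 for BMP and TGF-beta genes, where the direction in camera was down although the mean difference was 0.41.

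Basement membrane genes were on the higher side in endoderm, 8 of 11 of them in both experiments, with medians of 1.79 and 0.69. Agrin (Agrn) differed by 1.14 ± 0.31 (SE), laminin beta 1 (Lamb1) by 1.29 ± 0.39, and the collagen IV chains Col4a1 and Col4a2 by 1.48 ± 0.47 and 2.14 ± 0.76. Limma called 0 of them over the list alone and 0 over all genes, with 3 at an unadjusted p under 0.05, while the list had a camera adjusted p of 0.000143, and adjusted p = 0.342 with an estimated correlation, and without foregut endoderm 1 its mean fell from 0.99 to 0.62 (limma's adjusted p = 0.0356). In the mesenchymal matrix list, fibronectin (Fn1) was at 2.51 ± 0.42 and passed over the list alone, and the hyaluronan synthase Has2, at 3.14 ± 0.80, passed with the block. Fbn2 and Col5a2 of that list were at 0.73 ± 0.49 and -0.89 ± 1.15. The list, with a mean of 0.83, did not pass limma's camera (adjusted p = 0.0917), and its mean fell to 0.28 without foregut endoderm 1 (limma's adjusted p = 0.732) and to 0.02 without mesoderm and ectoderm 1 (0.843). It passed without foregut endoderm 2 (mean 1.38, adjusted p = 0.0272), without mesoderm and ectoderm 2 (1.64, 0.000928) in both other scalings (0.0193 with quantile normalization, 0.023 with median centring), without a filter (0.0361) and with the stricter filter (0.0275). With an estimated correlation, in limma's camera, the adjusted p was 0.712 with all arrays and 0.812, 0.593, 0.62, 0.583, 0.534 and 0.585 in those 6 settings.

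Cell cycle genes were close between the tissues, with medians of 0.01 and -0.17 over 17 members. The proliferation marker Mki67 was at 1.01 ± 0.29 (SE), Aurkb at -0.54 ± 0.33, Top2a at 0.43 ± 0.38 and Mcm6 at 0.36 ± 0.40. Of the immediate early and stress genes, 7 were measured, with Fos at 1.88 ± 0.67, Jun at 1.01 ± 0.41, Egr1 at 0.56 ± 0.40 and Hspa1b at -0.74 ± 0.63. Over either list alone, and over all genes, limma called 0 members, with 1 cell cycle gene and 0 stress genes at an unadjusted p under 0.05, and camera's adjusted p was 0.322 for both. With the stricter filter, which left 3 of the stress genes, their mean rose from 0.51 to 1.26 and limma's camera called the list (adjusted p = 0.0265, and adjusted p = 0.473 with an estimated correlation). Their mean was 0.33 without a filter and with median centring, 0.11 without mesoderm and ectoderm 1 and 0.91 without mesoderm and ectoderm 2, with no call in these settings (limma's adjusted p = 0.104, 0.292, 0.843 and 0.111).

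In all, limma's camera called 9 of the 20 lists, 6 higher and 3 lower in endoderm. With the replicate block it called 7, the WNT and FGF lists being lost. With an estimated correlation camera called 0, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.342, and fry called 0, with 5 at an unadjusted p under 0.05 and a lowest adjusted p of 0.103.

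The second comparison set the experiments against each other, with tissue as a term. Fau, a ribosomal protein gene, was higher in the second experiment by 5.01 ± 0.24 log2 units (SE), from 7.73 and 7.69 in endoderm and mesoderm and ectoderm of the first to 12.54 and 12.90 in the second. The small GTPase gene Rab24 (4.34 ± 0.21), Imp3 (4.23 ± 0.22), Rex1bd (3.95 ± 0.21) and the splicing factor gene Sf3b5 (3.84 ± 0.21) followed. On the lower side in the second experiment were Zfp207 (-2.99 ± 0.22), Synj2bp (-2.88 ± 0.23), Tmem209 (-2.85 ± 0.21), Dicer1, the RNase of microRNA maturation (-2.77 ± 0.23), and Pde4dip (-2.67 ± 0.23).

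Limma called 0 of 13288 probe sets between the experiments, the lowest adjusted p being 0.0966, while 2172 were higher and 1824 lower in the second at an unadjusted p under 0.05, against 664 in all by chance. For the 10 genes named the adjusted p was 0.102 each. The count depended on scaling and filter, with 733 called after quantile normalization (563 higher, 170 lower), 423 after median centring (340 higher, 83 lower) and 673 with the stricter filter. Epithelial junction genes were the only list past limma's camera, with a median 1.46 higher in the second experiment (adjusted p = 0.00062, and adjusted p = 0.81 with an estimated correlation).

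Control transcripts differed by experiment in the same way in both tissues. The Gapdh probe set at the 3' end exceeded the one at the 5' end by 6.45 and 7.04 log2 units in foregut endoderm 1 and mesoderm and ectoderm 1, and by 2.56 and 2.23 in foregut endoderm 2 and mesoderm and ectoderm 2. For Actb these values were 8.48, 8.88, 3.18 and 2.83. Such a gap widens where less of the 5' part of a transcript is labelled. The bacterial poly-A control transcripts, which are normally added before amplification and were read here at 4 probe sets, averaged 13.15 in the first experiment and 8.71 in the second, 21.7-fold apart, whereas hybridization controls averaged 11.11 and 11.29.

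**Figure D3:**
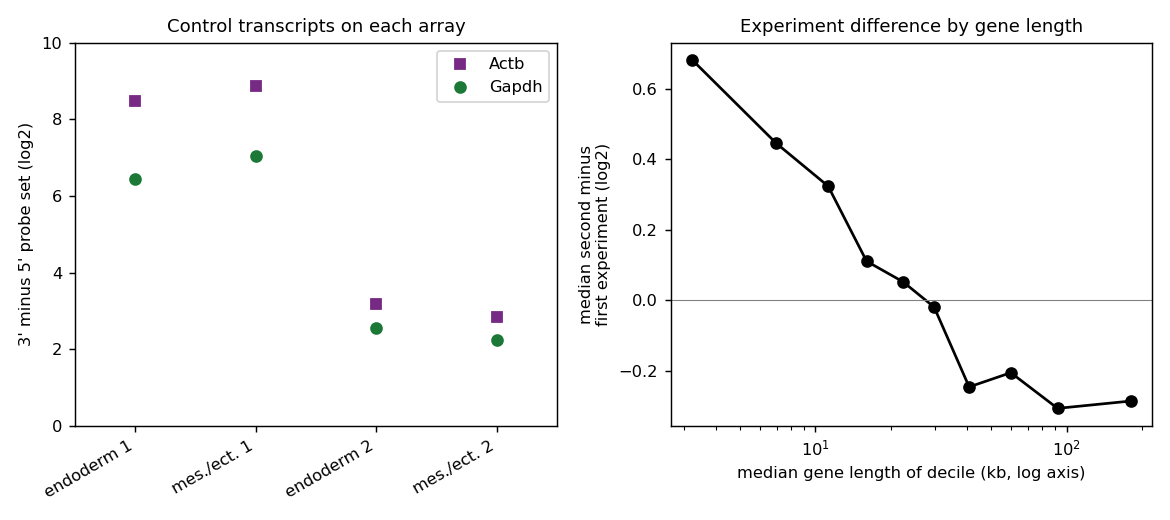
Left, log2 difference between the 3' and 5' probe sets of Gapdh and Actb on each array, from 6.45 to 8.88 in the first experiment and from 2.23 to 3.18 in the second. Right, median log2 difference between experiments (second minus first) of genes in 10 classes of gene length, against the median length of the class in kilobases on a log axis, from 0.68 in the shortest to -0.29 in the longest class.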

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

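Of the tests in this part, those of exchanged array labels, of heart-region tissue and of missing heart tissue were chosen after the result was seen, whereas the scaling test was set beforehand. Some results had opposite signs in the 2 experiments, and that difference was not tested, since each experiment holds 1 array per tissue. The difference between the experiments (first minus second, of foregut endoderm minus mesoderm and ectoderm, in log2 units) was 11.99 for the median of the heart list, 6.25 for red blood cells, 4.28 for endothelium and 3.81 for head and trunk mesenchyme. Smaller gaps with a change of sign were 2.74 for mesenchymal matrix genes, 2.14 for the retinoic acid list, 0.78 for BMP and TGF-beta genes and 0.18 for cell cycle genes. Among named genes the values were 10.71 for Tnni1, 8.98 for Myl2, 7.98 for Tbx20, 6.34 for Hbb-bh1, 6.15 for Hbb-y, 6.29 for Erg, 5.35 for Esam, 3.80 for Flt4, 0.63 for Egfl7, 3.87 for Col5a2, 1.47 for Fbn2 and 1.55 for Hspa1b.

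The heart and vessel genes and the 2 embryonic globins were the pattern weighed here. An exchange of the array labels within an experiment is argued against, since the foregut endoderm list kept a median of at least 3.29 in endoderm in both experiments, and scaling is too, since the heart median was still 4.83 in the first experiment and -6.97 in the second after quantile normalization. Heart-region tissue may have been collected with the endoderm in the first experiment, and heart tissue may have been missing from mesoderm and ectoderm 1. The heart, endothelial and red cell lists were fixed beforehand, but they were singled out because of this pattern. Their 29 measured genes lay a median of 3.27 higher in foregut endoderm 1 than in foregut endoderm 2. They lay a median of 5.13 higher in mesoderm and ectoderm 2 than in mesoderm and ectoderm 1. Of the 19 heart genes, 17 were higher in foregut endoderm 1 than in foregut endoderm 2, in part through the filter. All 19 were higher in mesoderm and ectoderm 2 than in mesoderm and ectoderm 1. Heart transcripts were thus mostly low in mesoderm and ectoderm 1 and present in foregut endoderm 1. These values go with both explanations, which do not exclude each other, and do not decide between them. Of the 29 genes, 10 lay above the filter in foregut endoderm 2, among them Isl1 and Tbx20 (10.82 and 9.93). Also among them were the sarcomere genes Myh7 (9.55), Myl3 (6.53) and Tnnc1 (6.32). No sorting step stands between dissection and RNA. The change in dissection, by hand alone or with enzymes, cannot be told apart from any other difference between the experiments, and no biological explanation was tested.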

How the results depend on the processing

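Of the alternatives here, only leaving out arrays for the count of 2-fold differences and the estimated correlation under other settings were chosen after the data were seen. Limma's count of 0 probe sets between tissues stayed at 0 in each of the alternatives run, with lowest adjusted p from 0.0847 without a filter to 0.9996 without foregut endoderm 1, and 236 to 865 higher at an unadjusted p under 0.05 with all 4 arrays and no block. In the simulation with an experiment effect, the fit without the block recovered 0% of the 16-fold changes. An unchanged count of 0 in settings without the block therefore says little about the tissues. With the replicate block the count of probe sets was 0, with 968 higher and 358 lower unadjusted. The lists called were then 7, and the block changed no call of another list, nor of a gene over all genes. The 607 probe sets 2-fold apart in both experiments became 169 at 4-fold, 353 with the stricter filter, and 820 to 1622 with an array left out, and stayed between 450 and 746 otherwise. The 9 called lists became 0 with an estimated correlation and 0 with fry, and 7 to 12 otherwise. Between experiments the 0 calls became 733 with quantile normalization, 423 with median centring and 673 with the stricter filter, which tests fewer probe sets, and stayed at 0 otherwise; the cause was not tested for the scalings, and no array could be left out for lack of residual degrees of freedom.

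Among lists, direction changed only in those that did not pass camera with all 4 arrays. It also changed in some named genes, and as 0 genes had passed over all genes, no called gene could change. The mesenchyme mean of 0.01 was -0.1091 with quantile normalization, -0.1698 with median centring, -0.4264 with the stricter filter and -0.0061 with probe sets averaged, the retinoic acid mean of -0.15 was 0.21 without a filter, and the endothelium mean of -0.17 was 0.0141 with a pseudocount of 16; the cause was not tested. With each array left out in turn, where a lone array is assumed to vary like the other group, means ranged from -1.37 to 1.39 for mesenchyme, -0.7586 to 0.4678 for retinoic acid, -4.33 to 3.37 for heart, -1.59 to 1.26 for endothelium, -2.38 to 1.27 for red blood cells, -0.08 to 0.0172 for cell cycle and -0.2826 to 1.10 for BMP and TGF-beta genes. Such ranges were -1.67 to 2.40 for Erg, -2.27 to 0.69 for Esam, -2.03 to 1.14 for Flt4, -0.49 to 0.15 for Egfl7, -2.67 to 1.15 for Hbb-bh1, -2.10 to 1.38 for Hbb-y, -0.0197 to 1.96 for Fgfr1, -2.34 to 0.55 for Col5a2, -1.51 to 0.0355 for Hspa1b, -1.32 to 6.94 for Tbx20, -6.35 to 0.54 for Myl2 and -7.07 to 1.22 for Tnni1. Of the 88 genes named between tissues, 34 had a log2 difference that moved by over 1.5 times with some array left out. These were the 12 above, those whose ranges stand beside their lists, and Fbn2 (0.23 to 1.22), Col4a2 (1.19 to 3.10), Aurkb (-0.74 to -0.33), Top2a (0.11 to 0.76), Mcm6 (0.01 to 0.71), Fos (1.14 to 2.61) and Egr1 (0.19 to 0.93). Of other list results, 11 lost and 11 gained a call, and of the genes named between experiments 20 results gained one, with quantile normalization or median centring. Signal near the floor limits dim genes most, as 41.3% to 44.7% of each array lay there.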

Other observations

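The named genes, the gene classes and the tests of this part were chosen after the values were seen. Apela, which encodes a peptide ligand of the apelin receptor, was 4-fold or more higher in both experiments (5.28 and 6.72), as were Kitl (2.90 and 2.60) and Rhou (2.41 and 2.18). Lower by as much were Eras (-5.81 and -3.65) and Pax6 (-4.75 and -3.73). With limma 0 of the genes in this paragraph passed over all 7802 genes, where 353 had an unadjusted p under 0.05, and 0 passed with the replicate block, where 902 had one.

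Within the heart genes, sarcomere genes and transcription regulators were set apart after their values were seen, so no test is given. Among members at or below a log2 value of 5 in foregut endoderm 2, the 7 sarcomere genes in foregut endoderm 1 lay a median of -5.002 from mesoderm and ectoderm 2, and the 6 regulators -0.30, a difference of 4.70. Of this, 3.84 remained after the median of each gene's length class was subtracted. That step removes only the average trend with genomic length and takes no account of probe positions, which were not available. It therefore cannot decide whether length or amplification accounts for the difference. The filter also left out heart genes high in mesoderm and ectoderm 2 alone. Whether foregut endoderm 1 may hold heart tissue diluted by endoderm, or heart-region cells of another stage or kind than mesoderm and ectoderm 2, is left open.

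The difference between the experiments ran with gene length. Across 7793 genes with a length, Spearman's rho between genomic length and the difference (second minus first) was -0.36, genes not being independent replicates, and class medians went from 0.68 for the shortest of 10 length classes to -0.29 for the longest. Together with the wider gap between 3' and 5' probe sets in the first experiment (a mean of 6.75 against 2.40 for Gapdh), this goes with a difference in RNA integrity or amplification. The length used was genomic and takes no account of transcript length or probe positions, so the trend by itself cannot decide the cause. A response to enzyme digestion in the second experiment stays open, as the immediate early and stress genes had a median of 0.0171 in endoderm and 0.52 in mesoderm and ectoderm, over 7 members, which went both ways in endoderm.

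Of the 3 ways to split the 4 arrays into pairs, the split by experiment gave 3609 probe sets at an unadjusted p under 0.05 in limma, the split by tissue 500 and the crossed split 172, with 0 past adjustment in each. The experiment was thus the larger structure of these arrays, and 3 splits are too few for a share under 0.05.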
